A study of Drosophila melanogaster with 3 samples.

How the data were processed

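The data are peak lists from chromatin immunoprecipitation with sequencing of 0 to 24 h old embryos of Drosophila melanogaster that carry E(spl)mβ tagged with enhanced green fluorescent protein, precipitated with an antibody against the tag, from fragments of 200 to 800 bp, per the labels. The labels give 3 biological replicates of 1 group, each from its own biosample. Per the provenance records deposited with the samples, peaks were called on dm6 for each replicate alone and for the pooled alignments, always against the same control alignment. The aligner, the peak caller and their versions are not given in the sources used here. Each replicate list and the pooled list held 30000 peaks. The IDR list held 8549, all of them in the pooled list, where they were exactly the 8549 peaks with the highest signal.

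The deposited lists give a signal per peak, computed by the authors relative to the control, and it was used only to rank, filter and describe peaks within a list. Median signals were 84.8, 43.1 and 49.6 in replicates 1, 2 and 3. The deposited −log10 q-value of each peak was read and not used for ranking, since it takes a single value throughout the IDR list. Summits were taken as the peak's start plus the deposited summit offset; 5 IDR summits lay at or past the end of their peak and were kept. A peak interval can hold several summits: the 8549 IDR peaks have 8236 distinct intervals. The files give no read totals, so depth is unknown, and intervals on shares cover counting of peaks, genes or windows only.

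The reference was the Release 6 assembly with the Ensembl release 115 annotation. Every peak on the arms ended within the length of its chromosome in that assembly. Analyses were limited to the arms X, 2L, 2R, 3L, 3R and 4, which left out 5 peaks of replicate 1 and no other peak. The annotation held 13945 protein-coding genes with 19607 TSSs on these arms. A gene was called bound when an IDR summit lay within 1000 bp of any of its TSSs. Summits were classed in the order promoter (within 500 bp of a TSS), 5′ untranslated region, coding sequence, 3′ untranslated region, intron and intergenic, and compared with 1000 sets of random positions on the same arms (permutation test, two-sided).

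Replicates were compared over the 8549 highest-signal peaks of each, with an overlap of at least 1 bp, and chance was taken from 100 circular shifts along each arm. Signal correlations used the highest overlapping peak of each replicate. The replicate signals and ranks given for single peaks are those of the replicate peak with the nearest summit within 100 bp, ranked among peaks on the arms. Peaks per arm were tested with exact binomial tests against arm length without undetermined bases.

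Gene lists (21, of which 4 by a rule on symbols), motifs (15), the tests and the alternatives were fixed before the data were examined. Lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, and motifs with Fisher's exact test between windows of 100 bp on each side of summits and of positions 1000 bp away, leaving out positions within 300 bp of an IDR summit, which left 15194 flank windows. P-values were adjusted by the method of Benjamini and Hochberg within each family, with a threshold of 0.05. In the Bearded list, BobB and BobC matched no gene. The symbols h, lgd and nct were matched through synonyms as hry, l(2)gd1 and Nct, and Dl and nos by their identifiers as Delta and nanos. Some genes stand in more than 1 list, such as hry, pnt, stumps, grh, esg and srp.

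Genes were named by a rule fixed beforehand: E(spl)mbeta-HLH, the gene with the TSS nearest to each of the 25 strongest IDR peaks, the 4 bound members of each list with the highest signal, and every member of the E(spl) complex and Bearded lists. A gene that this rule takes is not reported here. Other genes, such as the pathway members given as not bound and the genes with the most summits, were named after their values were seen.

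Alternatives were a stricter list (the 4274 strongest IDR peaks), peaks with support of all 3 replicates, peaks with support of both others after leaving out each replicate in turn, merged peaks, other overlap rules and list lengths, other distances to genes, 10000 random gene lists matched on length and number of TSSs, other window sizes and a dinucleotide-preserving shuffle. Peak sets without a replicate were subsets of the IDR list, which was made from all 3 replicates. Chosen after seeing the data were control windows matched on class, gene lists without the genes whose TSS lies within 50 kb of that of the tagged gene, and the tests of sites, regions and tRNA genes given among the other observations. For promoter summits, the control windows lay at the same offset from TSSs with no IDR summit within 1000 bp. For other summits, they were random positions of the same class and arm, more than 1000 bp from any IDR summit. There were no groups to compare, so no differences between groups were tested, and with 3 replicates no test for an outlying sample was run.

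The code was tested on simulated data. In 8000 windows with GGCACGTG planted in 2.70% of them, the motif test found a rise of 2.70 percentage points and called the motif, and with none planted it called 0 of 15 motifs. In simulated binding of 13945 genes, lists of 20 genes bound at 70% were called in 56.0% of trials and lists without an effect in 0.325%; in the matched test, planted lists bound at 90% were called in 100% of trials and lists of long genes in 0.400%. In 8000 peaks of which 60.0% were kept and the rest moved at random, the overlap was 64.6%. Of 4000 planted CAGTGYA sites, 80.3% pointed outward and 80.3% were found to. All scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.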

Results

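Chromatin immunoprecipitation with sequencing was used to map where the E(spl)mβ protein (gene E(spl)mbeta-HLH, FBgn0002733) binds in the Drosophila melanogaster genome. E(spl)mβ is a basic helix-loop-helix repressor of the Hairy and Enhancer-of-split family, whose gene is switched on by Notch signalling. The material was whole embryos of both sexes, 0 to 24 h old, of a line that carries a transgene encoding the protein with a green fluorescent protein tag at its C terminus, and the immunoprecipitation used an antibody against the tag. The samples form 1 group of 3 biological replicates, so no treatment, stage or genotype was compared. The data are peak lists, and control libraries were not analysed here. The read depth of the samples is unknown, so no value below carries an interval for depth. Coordinates are those of the dm6 build. Signal means the authors' own enrichment value per peak, which ranks peaks within a list and is not comparable between lists.

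The list of reproducible peaks, selected by the authors with the irreproducible discovery rate (IDR), held 8549 peaks on the chromosome arms. They fell into 7813 separate regions covering 3055240 bp, which is 2.29% of the arms. Peak widths ran from 118 to 3391 bp, with a median of 413 bp, and signals ran from 286.5 to 19605.9, with a median of 535.3. Of 13945 protein-coding genes, 4475 (32.1%) had an IDR summit within 1000 bp of an annotated transcription start site (TSS); these are called bound.

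The strongest peak of every list, the IDR list and each of the 3 replicates, lay at the promoter of E(spl)mbeta-HLH itself (3R, 26005046 to 26006023, minus strand). Its summit in the IDR list was at 3R 26006147, 124 bp upstream of the TSS, with a signal of 19605.9, and its signals in replicates 1, 2 and 3 were 9675.1, 4870.8 and 4982.9. A further summit in the same peak, at 26006375, ranked 8 with a signal of 8429.2. The IDR list held 12 summits within 5000 bp of the gene, among them a summit of signal 6333.4 at 26008644, towards E(spl)malpha-BFM, and summits of 3400.9 and 2698.7 at 26002714 and 26002921, downstream of the gene. The line carries the tagged gene on a transgene, whose extent and copy number are not given in the sources used here, and its share of the signal in this region was not measured.

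**Figure D1:**
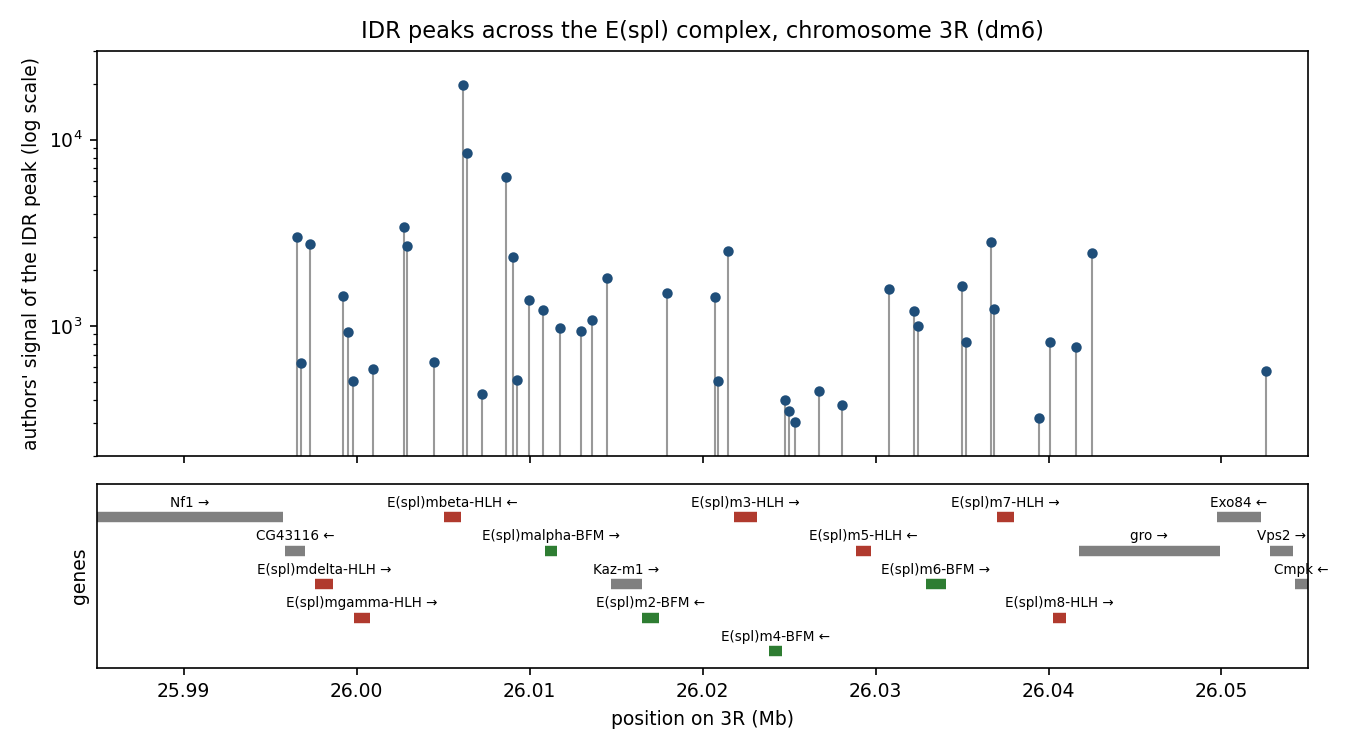
Summits of IDR peaks across the E(spl) complex on chromosome 3R. Each point is a peak summit at its dm6 position (Mb) and its height is the authors' signal on a log scale; bars in the lower panel are protein-coding genes, with the basic helix-loop-helix genes in red, the Bearded family genes in green and others in grey, and arrows giving the strand. The tallest point, 19605.9, is at the promoter of E(spl)mbeta-HLH.

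Elsewhere in the genome, the highest signals were at genes of many kinds. After E(spl)mbeta-HLH came a summit in an intron of CG11050 (2L 6612703, signal 12114.2), a summit 1397 bp upstream of the TSS of cbt, which encodes the zinc finger factor Cabut (2L 481085, 11558.2), and an intergenic summit whose nearest TSS, 5006 bp away, is that of CG4004 (X 12751323, 10977.1). The summit upstream of cbt was classed as intron and lies within the gene ush (2L 476220 to 540560). The promoter of Ugalt, a nucleotide sugar transporter gene, had a signal of 10525.3, and an intron summit of Trl, which encodes GAGA factor, had 9828.3. The 25 strongest peaks also lay nearest to mRpS10, which encodes a mitochondrial ribosomal protein (8743), px (8324.8), HmgZ, which encodes a chromosomal high mobility group protein (7749), Chro, which encodes the chromatin protein Chromator (7733.9), msi, which encodes the RNA-binding protein Musashi (7378.3), Gapdh2, which encodes a glycolytic enzyme (7242.4), Lk6, which encodes a kinase of the translation factor eIF4E (7145.2), gish, which encodes a casein kinase (7141.6), Mnn1, the menin gene (7126.5), and PNPase, which encodes a polynucleotide phosphorylase (7098.8). The other genes nearest to them were CG32772, CG18428, Fkbp14, CG18549, CG11309, CG14100, CG13390 and CG31871. Some of these summits had a TSS of a further gene within 1000 bp, so the nearest gene is not the only candidate. These further genes were eIF2Bbeta at Ugalt, Art3 at mRpS10, eIF4EHP at CG18428, Ssl1 at Chro, CG7632 at CG11309, CG17294 at CG13390 and Gprk2 at PNPase. Of these 25 peaks, 18 were at promoters, 6 in introns and 1 between genes, and every summit lay in a top-ranked peak of all 3 replicates.

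The replicates were compared over lists of equal length, the 8549 highest-signal peaks of each. Of the peaks of replicate 1, 82.9% overlapped a peak of replicate 2 and 80.3% a peak of replicate 3, and 84.7% of those of replicate 2 overlapped replicate 3. Lists shifted along the chromosome arms overlapped by 4.57%, 4.45% and 4.61% on average, with a highest value of 5.37% in 100 shifts. The intron peak of CG11050 and the peak upstream of cbt ranked 2 and 3 in replicates 1 and 2, and 4 and 6 in replicate 3. The summit at 26006375 ranked 5 in replicate 1, 6 in replicate 2 and 118 in replicate 3.

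Of the IDR peaks, 5799 (67.8%) had their summit in a top-ranked peak of all 3 replicates, 1929 in peaks of 2 replicates, 762 in a peak of 1 replicate and 59 in none. Full support fell with strength, from 98.0% of peaks in the strongest quintile to 12.6% in the weakest. This support counts only top-ranked replicate peaks, so a weak peak found lower in a replicate's list counts as unsupported there. Of the IDR peaks, 97.9%, 99.6% and 98.8% had their summit in a peak of the full lists of replicates 1, 2 and 3. At the bound genes of the lists described further on, elav (signal 4953.1), numb (3507.2) and aos (3378.3) had top-ranked peaks in all 3 replicates. Hey (336.7) and srp (352.9) had a top-ranked peak in 1 replicate. In the full lists, srp had a summit within 100 bp in replicates 1, 2 and 3, at ranks 8978, 12888 and 5173. Hey had such a summit in replicates 1 and 2, at ranks 5888 and 10224. Across IDR peaks, the signals of replicates 1 and 2 had a Spearman correlation of 0.860, those of 1 and 3 of 0.796 and those of 2 and 3 of 0.869; peaks are not independent replicates, so no p-value is given.

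Along the arms, chromosome 4, which is small and largely heterochromatic, held 16 peaks, or 12.0 per Mb (adjusted p = 4.1e-19, exact binomial test against arm length). The 3L arm held 70.4 peaks per Mb and was above its share of length (adjusted exact p = 6.2e-06), and 2R, at 60.2, was below it (adjusted p = 0.019). X, 2L and 3R held 62.0, 66.7 and 62.9 peaks per Mb, with adjusted exact p of 0.22, 0.11 and 0.39. The calls on 2R and 3L ended in the stricter list of the 4274 strongest peaks (exact binomial test, adjusted p of 0.18 and 0.076).

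IDR summits gathered at promoters and were nearly absent from coding sequence. Of the summits, 3569 (41.7%, exact 95% interval 40.7 to 42.8%) lay within 500 bp of a TSS, 3.64 times the 11.5% of random positions. Coding sequence held 17 summits (0.199%), against 13.9% of random positions, and 3′ untranslated regions held 72 (0.842%), against 4.47%. Introns held 3170 summits (37.1%, against 39.3%) and intergenic sequence 1682 (19.7%, against 30.1%). Promoter summits lay a median of 113 bp upstream of the nearest TSS, and 77.6% of them were upstream, as at E(spl)mbeta-HLH (124 bp), moody (160 bp) and aos (277 bp). Every class differed from random positions at p = 0.001998, the smallest that 1000 random sets can give in a two-sided permutation test. The promoter share was 54.7% in the strongest quintile and 33.6% in the weakest.

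**Figure D2:**
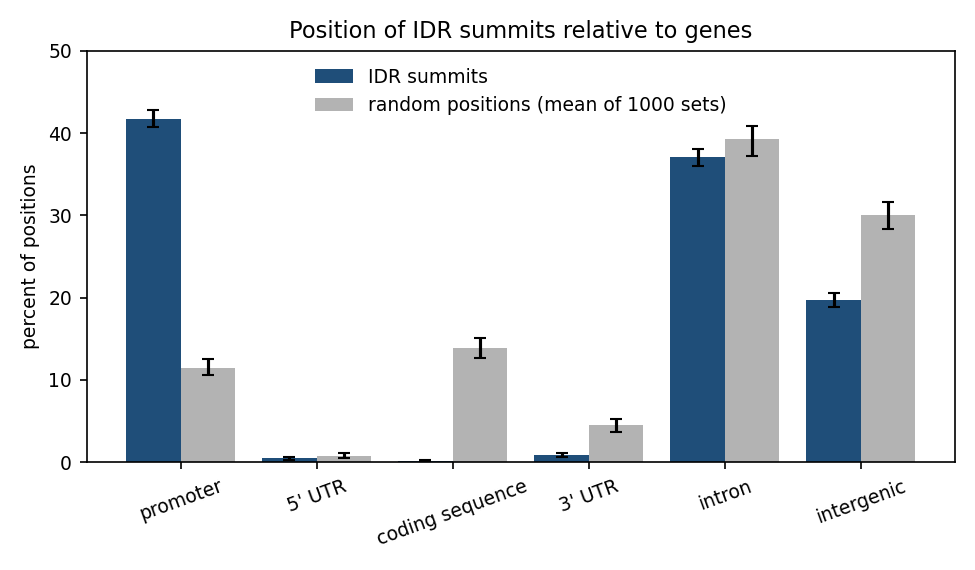
Percent of IDR summits (blue) and of random positions on the same arms (grey) in each class of sequence. Blue error bars are exact 95% intervals and grey error bars are the lowest and highest of 1000 random sets. Promoters hold 41.7% of summits and 11.5% of random positions, and coding sequence holds 0.199% and 13.9%.

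To ask which kinds of gene the protein binds near, 21 lists fixed beforehand were compared with all other protein-coding genes. Bound genes were more frequent in 7 lists and less frequent in 2 (Fisher's exact test, two-sided, adjusted over the 21 lists). The smallest p-values above the rest were those of the ribosomal protein genes, epidermal and fibroblast growth factor receptor signalling and the Notch pathway, and the chemoreceptor and cuticle protein genes were below it. Genes are not independent replicates, and neighbours can share a peak, so these p-values describe the lists and not a spread between embryos. Whether a gene is active in embryos was not measured here, and neither this comparison nor the matched random lists below account for it.

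Of the basic helix-loop-helix repressor genes of the E(spl) complex, which Notch signalling activates, 6 of 7 were bound (85.7%, against 32.1% of other genes, adjusted p = 0.019, Fisher's exact test). Besides E(spl)mbeta-HLH these were E(spl)m7-HLH (signal 2823.6), E(spl)mdelta-HLH (2736.7), E(spl)m3-HLH (2533.5), E(spl)mgamma-HLH (1449.6) and E(spl)m8-HLH (816.6), and E(spl)m5-HLH had no IDR summit within 1000 bp of its TSS. A summit of signal 1576.3 at 3R 26030772, upstream of E(spl)m5-HLH (26028854 to 26029735, minus strand), lay just beyond that distance. Its status as not bound therefore rests on the cutoff. Of the Bearded family, small proteins that dampen Notch ligand activity, 5 of 8 were bound (62.5%, adjusted exact p = 0.20): E(spl)m2-BFM (1502.1), E(spl)malpha-BFM (1381.1), E(spl)m6-BFM (1195.6), E(spl)m4-BFM (398.6) and Brd (336.2), and Tom, Ocho and BobA were not. Against random lists matched on gene length and number of TSSs, which were bound in 19.2% of cases, the Bearded list was above chance (adjusted p = 0.035, permutation test). Of the Bearded genes more than 50 kb from the tagged gene, 1 of 4 was bound. The whole E(spl) complex lies within 50 kb of the tagged gene, so the list of its repressor genes could not be tested apart from the transgene.

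Of the Notch pathway genes, 17 of 24 were bound (70.8%, adjusted p = 8.6e-04, Fisher's exact test), also above matched random lists (42.0%, adjusted p = 0.017, permutation test), and leaving out the region of the tagged gene gave 16 of 23 (adjusted p = 0.0015), an alternative chosen after the data were seen. The highest signals were at l(2)gd1, which acts in endosomal trafficking of Notch (4241), numb, which encodes an inhibitor of Notch (3507.2), gro, the co-repressor that Hairy and E(spl) proteins recruit (2456.8), and aph-1, a subunit gene of gamma-secretase (2358.8). The receptor gene N, the ligand gene Delta and the co-activator gene mam were also bound, and Su(H), H and Ser were not. Of the other Hairy and Hey family repressor genes, hry, which encodes Hairy (1179.5), Sidpn (835) and Hey (336.7) were bound and dpn and cwo were not (3 of 5, adjusted p = 0.44, Fisher's exact test).

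Genes of epidermal and fibroblast growth factor receptor signalling were bound in 15 of 18 cases (83.3%, adjusted exact p = 5.7e-05). They included aos, which encodes a secreted inhibitor of the epidermal growth factor receptor (3378.3), spi (3351.9) and Krn (2071.7), which encode ligands of that receptor, and stumps, which encodes an adaptor of fibroblast growth factor receptors (1733.1). Egfr, S and btl were not bound. Against matched random lists, bound in 48.1% of cases, the ratio was 1.73 (adjusted p = 0.015, permutation test), where it was 2.60 against other genes.

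Of the proneural and sense organ precursor genes, 6 of 15 were bound (adjusted exact p = 0.64), with chn (2044), ato, the proneural gene of chordotonal organs and photoreceptors (1250.7), da, which encodes the common partner of proneural proteins (625.2), and phyl (553.8) the highest; ase, sc and sens were not bound. Of the neuroblast genes, 11 of 21 were bound (adjusted exact p = 0.10), among them brat (3206.1), wor (1799.5), grh (1077.6) and esg (1057.6). Of the neuronal differentiation genes, 3 of 14 were bound (adjusted exact p = 0.64): elav, which encodes a neuronal RNA-binding protein (4953.1, rank 74), fne (578.9) and Syn (385.2). Against random lists matched on gene length and number of TSSs, which were bound in 57.7% of cases, this last list was below chance (adjusted p = 0.035, permutation test).

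Of the glial genes, 7 of 10 were bound (adjusted exact p = 0.041), including moody, which acts in the blood-brain barrier (2068.5), Gs2, a glutamine synthetase gene (1572.2), loco (792) and pnt (756.6). Of the mesoderm and muscle genes, 12 of 21 were bound (adjusted exact p = 0.043), including tin, which is needed for heart formation (2490.5), and kirre (1339.2) and mbc (1274), which act in myoblast fusion. Of the cell cycle genes, 10 of 15 were bound (adjusted exact p = 0.028), including CycE (2980.6), Cdk1 (1406.7), aurA (1086.5) and E2f1 (861.1). These 3 calls ended against matched random lists (adjusted p of 0.50, 0.58 and 0.13, permutation test) and among the 5799 peaks with support of all 3 replicates.

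Other lists of tissues and of patterning did not pass the test. Bound were 8 of 13 tracheal and ectodermal tube genes (adjusted exact p = 0.065), with trh highest (1996.8) and shg at 594.9, and 9 of 20 segmentation genes (adjusted p = 0.35), with hry, opa (607.8), ptc (520.1) and wg (478.2) highest. Of the Hox genes and cofactors, 3 of 10 were bound, namely Dfd (392), hth (377.4) and Antp (305), with an adjusted p of 1 in Fisher's exact test. The germ line list had 4 of 12, with gcl (1153.9), bgcn (1062.3), nanos (974.7) and vas (807), and an adjusted exact p of 1. The gut list had 5 of 12 (adjusted exact p = 0.64), with fkh (983.8), peb (542.2), cad (393.6) and dve (375.3) highest. The haemocyte and fat body list had 2 of 13 (adjusted exact p = 0.35), srp (352.9) and ush (349.1), and the Jonah proteases of the gut 1 of 16 (adjusted p = 0.062), Jon65Ai (292.6). The summit of 11558.2 within ush lay more than 1000 bp from its TSSs and is not counted there. The protease list was called lower without replicate 3 (adjusted exact p = 0.025), within 500 bp of a TSS (0.028) and by gene body (0.023), and not against matched lists (0.58).

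Of the cytoplasmic ribosomal protein genes, 77 of 92 were bound (83.7%, exact 95% interval 74.5 to 90.6%, adjusted p = 2.5e-23), among them RpL11 (2942.5), RpL34b (2715.3) and RpL34a (2222.9). The median signal of the bound genes among them was 920.7, against 713.1 over all bound genes. The 15 that were not bound included RpL5, RpL9, RpL10, RpL15, RpS2 and RpS27A, and paralogs of other genes of the list such as RpL22-like and RpS5b. Of the olfactory, gustatory and ionotropic receptor genes, which act in sensory neurons, 4 of 179 were bound (2.23%, adjusted exact p = 2.5e-23), namely Gr32a, Or88a, Or49a and Or9a. Of the cuticle protein genes, 8 of 116 were bound (6.90%, adjusted exact p = 5.5e-10), with Cpr73D (1276.3), Cpr65Ay (959), Cpr67Fb (922.3) and Cpr23B (503.4) highest.

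**Figure D3:**
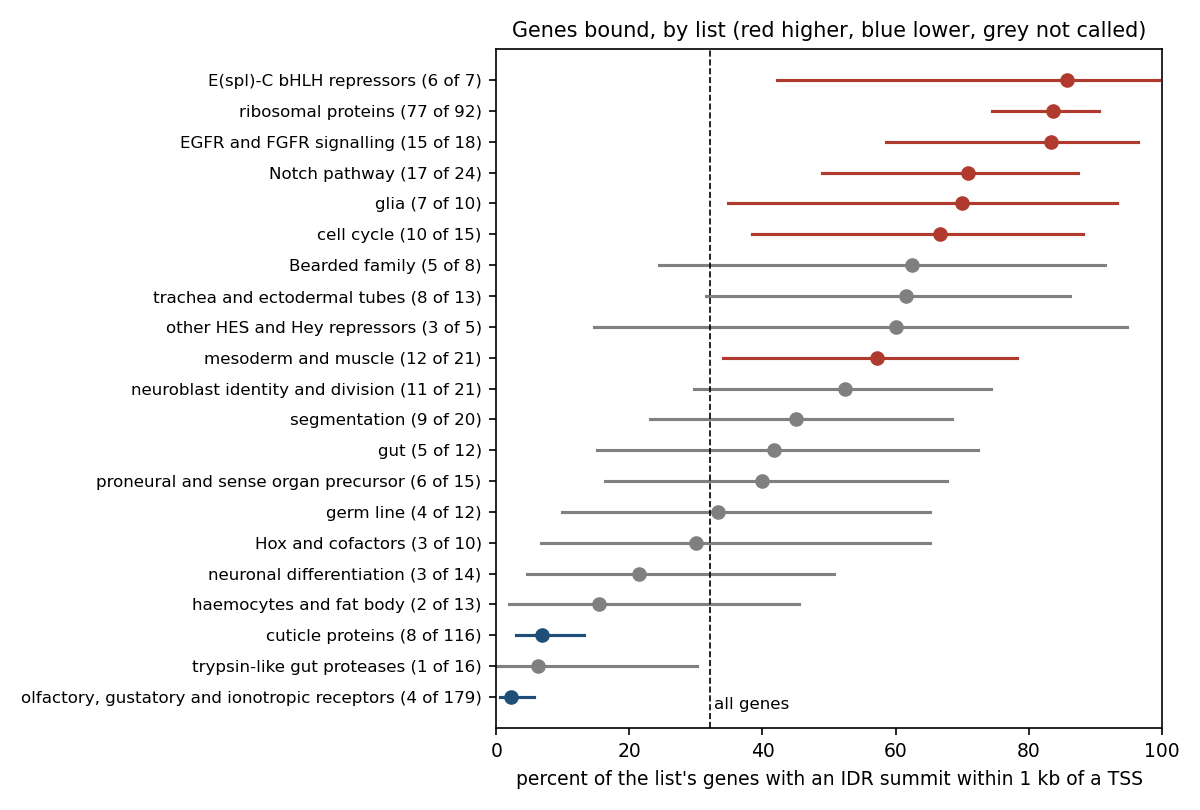
Percent of the genes of each list with an IDR summit within 1 kb of a TSS (x axis), with exact 95% intervals as bars and the counts beside the names. Red lists were bound more often than other genes, blue lists less often, and grey lists were not called; the dashed line is the share of all genes, 32.1%.

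Short sequences known from Hairy and E(spl) proteins and from other factors were counted in windows of 100 bp on each side of IDR summits and of flanking positions 1000 bp away. The E-box CACGTG, to which E(spl) repressors bind, was in 4.07% of summit windows and 2.47% of flanks (odds ratio 1.67, adjusted exact p = 3.1e-11). Its extended form GGCACGTG was in 1.30% and 0.336% (odds ratio 3.91, adjusted exact p = 1.1e-16), and the Hairy-type site CACGCG in 7.23% and 4.35% (odds ratio 1.71, adjusted p = 7.2e-20). Against these flanks, the largest odds ratios were those of core promoter elements: TATCGATA, the DNA replication-related element, with 2.95% against 0.50% (odds ratio 6.04, adjusted exact p = 8.6e-51), and GGTCACAC, the site of M1BP, with 1.98% against 0.382% (odds ratio 5.26, adjusted p = 2.5e-31). Against control windows of the same class, an alternative chosen after the data were seen, the ratio of shares was 2.004 for TATCGATA (5.89 with flanks) and 1.698 for GGTCACAC (5.18 with flanks), and that of GGCACGTG, 4.36, was the largest. Distance to a TSS was matched for promoter summits only, and their controls were at TSSs with no IDR summit within 1000 bp. In the stricter list, with flanks, TATCGATA was at 6.12, GGCACGTG at 3.53 and GGTCACAC at 3.19. GGCACGTG was at 2.41 with windows of 200 bp and at 6.53 against shuffled windows, where TATCGATA was at 13.3 and GGTCACAC at 8.45. All tests were Fisher's exact tests, two-sided, adjusted over 15 motifs. They treat windows as independent and do not use the pairing of a summit with its own flanks. Neighbouring summits can also lie close together, so these p-values describe the windows and not a spread between embryos.

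Of the other motifs, 3 were more frequent at summits: GAGAGAG of GAGA factor (4.49% against 3.36%, adjusted p = 1.9e-05, Fisher's exact test), CATATG of Twist type (7.19% against 6.23%, adjusted p = 0.0057) and the AT-rich TTTATTG (10.2% against 8.50%, adjusted p = 1.9e-05). The N-box CACNAG, also a known E(spl) site, was less frequent (19.0% against 22.9%, adjusted p = 1.9e-12, Fisher's exact test), as were the proneural-type E-box CAGSTG (12.1% against 16.5%, adjusted p = 4.2e-20), any E-box CANNTG (59.3% against 64.8%, adjusted p = 4.4e-17) and the ETS site CCGGAA (3.21% against 6.06%, adjusted p = 1.1e-22). The sites YGTGRGAA of Su(H) (2.2% against 2.13%), CAGGTA of Zelda (4.25% against 4.50%) and TCAAGTG of Tinman type (3.68% against 3.96%) did not pass the test. Against shuffled windows with the same dinucleotides, CAGSTG and CANNTG were more frequent at summits, 1.66 and 1.14 times, so their direction depends on the background, and YGTGRGAA (1.30 times), TCAAGTG (1.77) and CAGGTA (0.791) passed the test there, the last of them as less frequent. The GAGAGAG call ended in the stricter list (ratio 0.940, adjusted exact p = 0.57), without replicate 1 (1.14, adjusted p = 0.14) and without replicate 2 (1.14, adjusted p = 0.14), and also with support of all 3 replicates (1.18, adjusted p = 0.054) and with windows of 50 bp (1.18, adjusted p = 0.12). It was kept without replicate 3 (1.40), with windows of 200 bp (1.99), against shuffled windows (4.63) and against controls of the same class (1.46). The lists without a replicate are subsets of the IDR list, whose summits and signals still include that replicate, so they do not isolate its contribution. TTTATTG and CATATG each lost the call under 1 alternative.

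**Figure D4:**
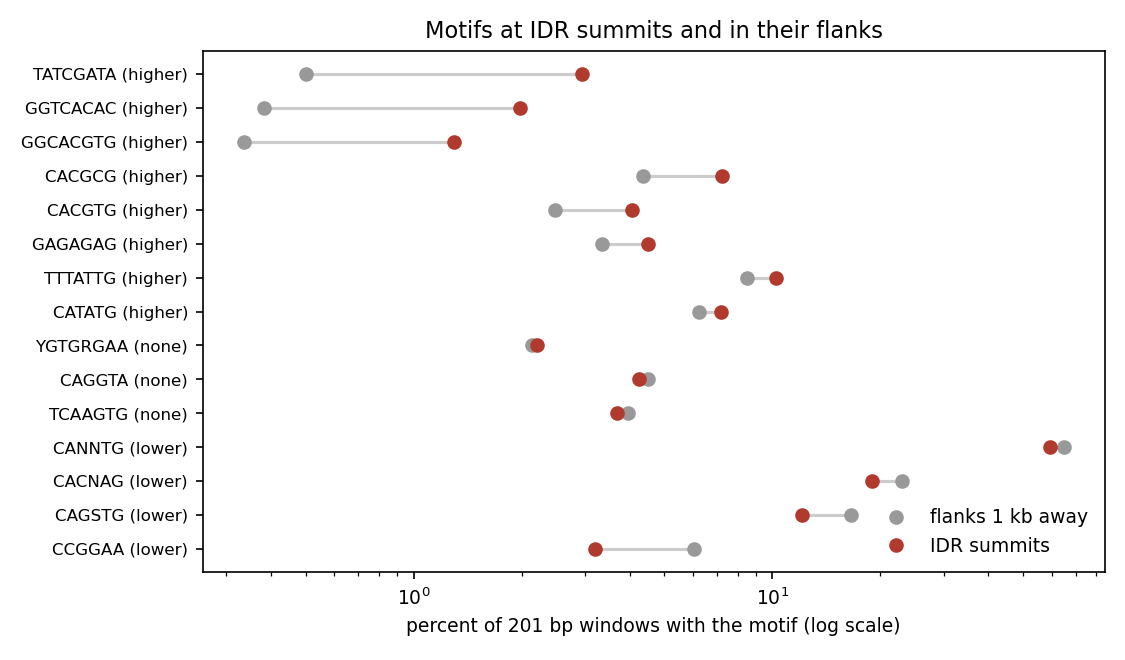
Percent of windows that hold each motif, on a log scale, at IDR summits (red) and in flanks 1 kb away (grey). The words beside the motifs give the call of Fisher's exact test; TATCGATA is at 2.95% of summits and 0.50% of flanks, and GGCACGTG at 1.30% and 0.336%.

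For CACGTG, the difference between strong and weak peaks did not pass the test. The site was in 3.63% of windows in the strongest quintile (exact 95% interval 2.79 to 4.62%) and 4.56% in the weakest (3.62 to 5.66%), with an odds ratio of 0.787 (p = 0.20, Fisher's exact test), which turned to 1.07 without replicate 1 and fell to 0.672 without replicate 3 (p = 0.042). Among the 99 peaks of named genes, 8 held the site. At ato the site lay 2 bp from the summit in the sequence CGGGCGGCACGTGCTGCCTT (3R 8277927 to 8277946). Mnn1, wor and esg also held the extended form, and E(spl)m6-BFM, Brd, Hey and RpL11 held CACGTG alone. The promoter peak of E(spl)mbeta-HLH held no CACGTG within 100 bp of its summits at 26006147 and 26006375.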

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

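No test was run on the result given here, which was noticed only after the data were seen. The list of replicate 1 held 5 peaks on the mitochondrial genome, which lies outside the chromosome arms that were analysed, and the lists of replicates 2 and 3 held 0. They stood out because any peak there is signal in data that no comparison used. The strongest had its summit at position 1815 with a signal of 7842.8, rank 2 of all peaks in replicate 1, followed by summits at 3552 (6160.2, rank 3), 2014 (3603.8, rank 17), 406 (1189.7, rank 333) and 2737 (619.5, rank 1100). The mitochondrial genome was not in the pooled or the IDR list.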

How the results depend on the processing

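The alternatives were fixed before the data were examined, except the control windows matched on class and the lists without the region of the tagged gene, which were chosen after seeing the data. No paired analysis was possible because there is only 1 group. The promoter share stayed above random positions throughout, at 29.0% within 200 bp of a TSS and 50.3% within 1000 bp. Of 188 values for single gene lists under an alternative, 150 kept direction and side of the threshold, 20 lost the call, 5 gained one and 13 turned; of 135 for motifs these were 121, 6, 2 and 6, and of 36 for arms 30, 2, 2 and 2. The cause of a change was not tested unless the alternative itself, such as fewer peaks, shows it.

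The IDR list had 4274 peaks in the stricter form. Within 2 kb of the tagged gene lay 4 summits and within 10 kb 22. Replicate overlap was 65.1% at 50% reciprocal overlap and 73.4% for summits within 100 bp, and 79.3 to 83.7% leaving out each replicate. Support by all 3 replicates was 63.5% for summits within 100 bp, 36.9% and 91.0% for the shorter and longer replicate lists, 93.8% for the stricter IDR list, and 74.0 to 76.6% leaving out each replicate. The correlation ran from 0.796 to 0.869 leaving out each replicate. With 1 replicate left out a single pair remains, so these correlations and the overlap range above are values of single pairs and not a further check. The number of lists bound more often fell from 7 to 4 in the stricter list, to 4 with all 3 replicates and to 4 to 5 leaving out each replicate; glia and mesoderm were lost in each of these, and E(spl) complex, Notch pathway, growth factor receptor signalling and ribosomal proteins were kept. The odds ratio of CACGTG by strength ran from 0.672 to 1.07 leaving out each replicate.

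Values that turned were mostly near 1 and not called. As ratios to the background, leaving out each replicate, 3R peak density ran from 0.985 to 1.01 (1.00 with all 3 replicates; without replicate 3, X at 0.937 and 2L at 1.055 gained a call, with adjusted exact p of 0.037 and 0.049), proneural genes from 0.992 to 1.28, segmentation from 0.930 to 1.30, Hox from 0.742 to 1.12 and gut from 0.928 to 1.24. In the stricter list segmentation was at 0.483, gut at 0.805 and GAGAGAG at 0.940. By gene body neuronal differentiation was at 1.11 and Hox at 1.55, and within 500 bp Hox was at 1.07. Against matched lists germ line was at 0.848 and gut at 0.997, and without the region of the tagged gene the Bearded family was at 0.781. YGTGRGAA was at 0.987 with windows of 50 bp and TCAAGTG at 1.03 with 200 bp. Against shuffled windows CAGSTG was at 1.66, CANNTG at 1.14 and TCAAGTG at 1.77. With controls matched on class, all 12 motif calls were kept, but ratios fell from 5.89 to 2.004 for TATCGATA and from 5.18 to 1.698 for GGTCACAC, and that of GGCACGTG, 4.36, became the largest. Depth is unknown, so whether it limited which weak peaks were called in any replicate could not be tested.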

Other observations

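Apart from the matched random gene lists, which were fixed beforehand, all tests in this part were chosen after the results they concern were seen. The genes with the most summits in the gene body were long: the muscle founder cell gene kirre held 33 over 394149 bp (0.837 per 10 kb), rdx, sbb and shn held 20 each, CG1677, the ecdysone-induced gene Eip75B and the Wingless receptor gene fz2 19 each, the Notch co-activator gene mam and sick 18 each, and the ETS factor gene pnt 17 over 55937 bp (3.04 per 10 kb). No test of these counts against gene length was made. In bins of 50000 bp, which held 3.19 summits on average, the bin with tara held 27 and a bin on 3L with Diap1, mib1 and Notum held 23. Of 290 tRNA genes, 39 (13.4%, exact 95% interval 9.74 to 17.9%) had an IDR summit within 500 bp, against 5.83% of random positions (p = 0.001998, the smallest that 1000 random sets can give, permutation test). Neighbouring tRNA genes can share a summit. The random positions were drawn independently, without a match on such closeness or on distance to promoters, so the p-value and interval do not account for these.

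Within summit windows, the extended E-box GGCACGTG lay close to the summit: 45.6% of sites (exact 95% interval 36.7 to 54.7%) were within 25 bp, against 25.8% for an even spread (adjusted p = 2.6e-05, exact binomial test) and 20.6% in controls matched on class. For all CACGTG sites, which include the extended form, the share was 31.2% (adjusted exact p = 0.046) and for CACGCG 30.5% (adjusted p = 0.016), while TATCGATA, at 24.2%, and GGTCACAC, at 24.6%, did not pass this test. The 246 CACGTG sites outside the extended form had 25.6% within 25 bp, against 25.5% for an even spread (p = 1, exact binomial test), so the extended sites carry the centring. TCAAGTG (18.9%) and CANNTG (24.2%) lay there less often (adjusted exact p of 0.016 and 0.021). GGCACGTG was enriched at promoters (odds ratio 3.53 against matched controls, adjusted p = 4.1e-07) and at intron and intergenic summits (4.86, adjusted p = 1.2e-19), whereas TATCGATA passed the test at promoters (2.30) and not at intron and intergenic summits (1.10, adjusted p = 0.69), all by Fisher's exact test.

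The E(spl) complex held 36 summits in the 50000 bp from 3R 26000001 to 26050000, more than any other bin. Extra copies of the tagged region that raise signal along its whole length stay open: 0 summits lay in coding sequence, where its share of the region gives 5.69, but IDR summits avoid coding sequence everywhere, and at their general share of 0.526% (45 summits, counted here whatever their class, so that coding sequence near a TSS is included) only 0.189 would be expected, so this test decides nothing. Extra copies that multiply peaks present anyway stay open too: the signal of the tagged promoter was 1.62 times the highest signal outside the region, and 27 of the 36 summits would stay above the lowest IDR signal if divided by 2. What keeps both open is that the copy number is not given in the sources used here and no library without the transgene was analysed here. No biological explanation was tested, as the samples form 1 group.

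Ribosomal protein genes were bound far more often than other genes, at 83.7%. Gene length and number of TSSs do not account for this, since matched random lists were bound in 32.01% of cases (adjusted p = 0.0014, permutation test). A signal of active promoters in general, without the E-box CACGTG, stays open: 10.9% of the ribosomal protein promoter summits held CACGTG, against 3.94% of other promoter summits (adjusted exact p = 0.0075) and 2.24% of windows at unbound promoters, so the site is more frequent there yet most summits lack it. TATCGATA was in 25%, against 5.90% of other promoter summits (adjusted exact p = 3.1e-08). No biological explanation was tested.

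At intron and intergenic summits, the 7-mer most enriched over flanks was CAGTGTA, in 10.9% against 2.35% of windows. Sites of CAGTGYA in the 3 bins of 25 bp that begin 50 bp from such a summit pointed away from it in 86.2% of cases (786 against 126), at promoters in 70.7% and around flanking positions in 49.5%; 14.2% of the intron and intergenic summits had such an outward site in these bins, and outward sites on both sides were found at 89 summits where 31.1 were expected (p = 7.4e-22, Fisher's exact test). Base composition is argued against as the whole cause by 7-mers of the same letters in another order. These were counted only if they held neither CAGTG nor CACTG and had at least 20 sites. Of their sites, 49.1% pointed outward in the median and 62.6% at the 95th percentile, although the highest of 1201 reached 86.1%. Pyrimidine runs were also uneven, from 66.9% for TTTTTTT to 82.2% for TTTTCTC. The reordered 7-mers include pieces shifted along the site, such as AGTGCAT at 82.1%, and their share of the high values was not counted. Scaled to the square root of the number of sites, the outward excess was largest for TTTTTTT (1858 against 921), above CAGTGTA (369 against 38). Some 7-mers with CACTG, which is CAGTG read on the other strand, also pointed outward, such as CCACTGT (334 against 57) and CACTGTA (246 against 57). The direction is therefore that of the longer sites and not of CAGTG as such. Splice acceptors of annotated introns are argued against by the 0.382% of outward sites near such a site, and 0% lay in an annotated transposable element or in a sequence of 47 bp found again in identical form. Copies of a repeated element that have diverged stay open, since 37.0% of outward sites (exact 95% interval 33.6 to 40.5%), against 11.6% of sites in flanks, lay in sequence masked as repeats in the reference; no biological explanation was tested.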
